A study of Mus musculus with 12 samples.

How the data were processed

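RNA was measured by bulk sequencing in 12 mouse libraries: 3 of mesenchymal stem cells (MSCs) from p53 wild-type (WT) mice, 3 of MSCs from p53 knockout (KO) mice and 6 of tumors from p53 knockout mice. Per the labels' protocols, MSCs were sorted as cells negative for CD45, Ter119 and CD31 and positive for the leptin receptor (LepR) and for CD140a, the receptor PDGFRA. Tumor RNA was extracted with TRIzol, and no sort of tumor cells is described there, although the labels give the cell type of these libraries as tumor cell. Whether tumor cells were enriched is therefore unknown. All RNA was copied with a low-input cDNA kit (SMART-Seq v4), sheared by ultrasound and made into libraries with a kit that does not mark strand. Per the submitters' processing notes, TopHat2 2.0.13, Cufflinks 2.2.1, Cuffdiff and the mouse genome build mm10 were used. The steps between alignment and the deposited values are not given in the sources used here.

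The main values are the log2 values of 24421 genes that the authors deposited in a table titled as variance-stabilized and batch-adjusted. This scale follows log2 expression for well-expressed genes and flattens to a floor for genes with few reads, so changes of low genes are understated. A total of 1451 genes had the same value, 4.75, in every library. Exactly shared floor values divided the libraries into 2 batches. Batch 1 held the libraries labelled WT_MSC 1 and KO_MSC 1 and tumors 1 to 3, and batch 2 held WT_MSC 2 and 3, KO_MSC 2 and 3 and tumors 4 to 6. The floors of both batches lay the same distance from the common floor in 100% of 8352 genes (tolerance 1e-05), by up to 1.92, as an added and subtracted shift leaves them. A gene without reads can therefore have different values in the 2 batches.

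The authors' other deposited table is titled as normalized counts, but its values are a score and not counts. Each score equals 100 times the stabilized value, rounded and divided by 1 factor per library, for 100% of its 18949 genes (tolerance 0.01). Reads could not be recovered from either table, so the depth per library is unknown, no counting interval is given and no count test was possible. The test planned was limma on the logarithm of normalized counts with a pseudocount and a minimum mean. Since the values were already logarithms, limma was run on the stabilized values with no pseudocount, the 18949 genes of the other table served as the filter, and that table became an alternative.

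Each comparison was fitted on its own groups with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided, no covariates and no block). Benjamini-Hochberg adjustment ran over the 18948 genes that varied, and an adjusted p under 0.05 passed. The labels do not say which libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical. The p-values of fits without a batch term take no account of the earlier batch adjustment and can be too small. Tumors divide between the batches otherwise than MSCs, so a batch shift need not cancel in comparisons with tumors. By chance, groups of 3 and 3 do not overlap in 10% of genes, and groups of 3 and 6 in 2.38%.

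The comparisons, the test, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The 23 lists held 326 genes, of which 319 were tested. They were p53 target genes, LepR+ marrow stromal identity, osteoblast genes, adipocyte genes, chondrocyte genes, myogenic program, mature skeletal muscle, smooth muscle genes, proliferation, extracellular matrix, mesenchymal transcription factors, hypoxia and glycolysis, interferon response, inflammatory secretory genes, immediate early and heat shock genes, ribosomal protein genes, genes altered in sarcoma, sex-linked genes, and markers of macrophages, neutrophils and granulocytes, lymphocytes, erythroid cells and endothelial cells. Lists were tested against all other genes with camera at a preset correlation of 0.01, adjusted over the 23 lists, again with an estimated correlation, and with fry, which tests whether a list moves on balance in 1 direction. No call of camera held with an estimated correlation in the fits without a batch term, and with it 1 list was called so, stromal identity in tumor against WT MSC (0.0480). Fry called 0, 8 and 7 lists for KO against WT MSC, tumor against KO MSC and tumor against WT MSC.

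The named genes of a comparison were the 10 higher and 10 lower passing genes with the largest changes, a mean of at least 6.64 (log2 of 100) in the higher group, no overlap between groups and an ordinary symbol. Where none passed, the 5 genes with the smallest unadjusted p were taken. Trp53 and up to 4 members of each list with the smallest adjusted p were added, and the text names part of these. Some genes that the rule took are not reported here. Among tumors, the rule took the 10 genes with the largest SD and a value of at least 8.97 (log2 of 500) in 1 tumor or more.

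The fit was tested on simulated data with 200 changed genes. Of 66 genes changed by 4 log2 units, 42.4% were recovered for KO against WT MSC, 86.4% for tumor against KO MSC and 92.4% for tumor against WT MSC. Of 67 genes changed by 2 log2 units, the shares were 1.49%, 23.9% and 43.3%. Among unchanged genes 0, 6 and 8 were called. Genes were drawn independently, and the shares depend on how many genes change, so they may differ in data with more changed genes. Alternatives were no filter, a filter at a mean of log2 of 50, median, upper-quartile and quantile scaling, the other table, all 12 libraries in 1 fit, library weights, a robust spread, a fold threshold, a replicate block and the removal of each library. A batch term, batch 2 alone and centring of the tumors were added after the data were seen. Gene positions are from GENCODE's annotation of GRCm38, the assembly of mm10. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.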

Results

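Bone marrow stromal cells of p53 wild-type mice were compared with those of p53 knockout mice, and both with sarcomas from bone or bone marrow of knockout mice. LepR+ CD140a+ MSCs are marrow stromal cells that lie around blood vessels and support blood formation. There were 3 WT MSC, 3 KO MSC and 6 tumor libraries. The values are deposited stabilized log2 values of unknown depth. The number of genes at the floor was 2569 in the library labelled KO_MSC 1 and 3594 in WT_MSC 1. In the other libraries it ranged from 8886 in tumor 2 to 12313 in the library labelled KO_MSC 3. Across genes, which are not independent replicates, correlations lay between 0.939 and 0.974 among WT MSC libraries, between 0.797 and 0.930 among KO MSC libraries and between 0.842 and 0.949 among tumors. The library labelled KO_MSC 3 stood apart in its low values. Of 2522 genes with a WT mean between 7 and 8, 22.3% were below 5.5 in it, against at most 6.86% in any other library. Rn45s, the ribosomal RNA precursor and chosen here after its values were seen, had the highest value of all genes in the libraries labelled KO_MSC 2 and KO_MSC 3. It was at 16.78, 16.39 and 16.045 in WT_MSC 1, 2 and 3 and at 17.92, 17.50 and 19.75 in the libraries labelled KO_MSC 1, 2 and 3, a difference of 1.98 ± 1.48 that did not pass (adjusted p = 0.732, limma). In tumors 1 to 6 it was at 16.37, 16.54, 16.39, 13.35, 17.60 and 15.765.

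Trp53, which encodes p53 (chromosome 11, 69580359 to 69591873, plus strand), went against the label in 2 of the 3 libraries labelled KO MSC. Its value was 9.96, 10.04 and 10.61 in WT_MSC 1, 2 and 3. It was 10.49 and 9.76 in the libraries labelled KO_MSC 1 and KO_MSC 2, and 6.96 in the library labelled KO_MSC 3. Tumors 1 to 6 had 7.56, 7.80, 8.72, 9.16, 7.19 and 6.79. Trp53 fell by 2.33 ± 0.51 (SE, n = 3 and 6) in tumors against WT MSC (adjusted p = 0.00901, limma), and without WT_MSC 3 its change was -2.13 (adjusted p = 0.0506, limma). In batch 2 alone it was -2.61 (adjusted p = 0.103, limma). In libraries labelled KO MSC against WT MSC its change of -1.13 ± 0.84 did not pass (adjusted p = 0.731, limma), and it was -0.08 without the library labelled KO_MSC 3 and -1.84 without the library labelled KO_MSC 1. In tumors against libraries labelled KO MSC its change of -1.20 ± 0.76 did not pass either (adjusted p = 0.331, limma), but it passed with library weights (-1.77, adjusted p = 0.0169, limma), whose estimation did not converge in 2 of the 3 comparisons. Trp53 was at -0.49 without the library labelled KO_MSC 1 (adjusted p = 0.783, limma), and at -2.255 without the library labelled KO_MSC 3 (adjusted p = 0.0530, limma). The labels do not say which part of the gene was deleted, and a value per gene includes reads from any exon that remains. Every direction below that involves KO MSC rests on these labels.

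**Figure D1:**
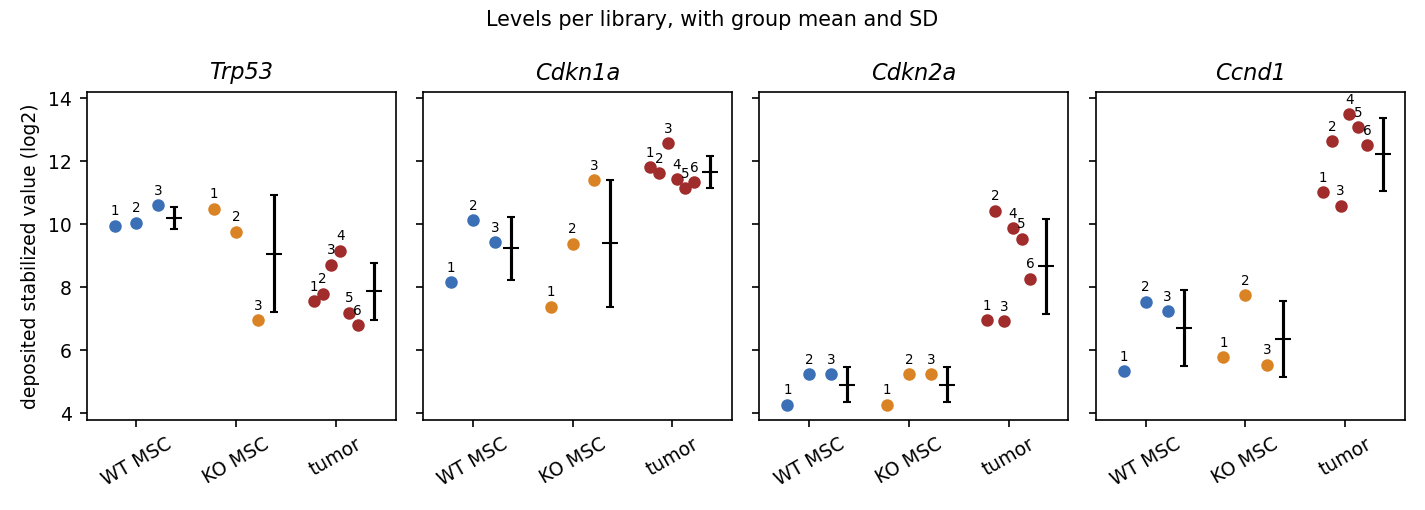
Deposited stabilized values (log2) of Trp53, Cdkn1a, Cdkn2a and Ccnd1 in each library (points), with the mean and SD of each group (n = 3, 3 and 6). Trp53 lies at 10.49 and 9.76 in the libraries labelled KO_MSC 1 and KO_MSC 2, beside WT values of 9.96 to 10.61.

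The first comparison asked how sorted stromal cells of knockout mice differ from those of wild-type mice. Stromal identity and extracellular matrix genes had lower values in the libraries labelled KO MSC and ribosomal protein genes had higher values, but no single gene passed. All 18 stromal identity genes were lower, among them the growth factor receptor Pdgfrb (-2.31 ± 0.50), the macrophage growth factor Csf1 (-1.84 ± 0.42) and the transcription factor Ebf1 (-1.82 ± 0.45; SE, n = 3 and 3). Of 19 extracellular matrix genes 18 were lower, among them the collagen genes Col6a2 (-2.80 ± 0.57) and Col6a1 (-2.62 ± 0.57), the matrix protease Mmp14 (-2.35 ± 0.57) and the fibrillin gene Fbn1 (-1.79 ± 0.45). Limma called 0 of 18948 genes (lowest adjusted p = 0.551). At an unadjusted p under 0.05 there were 1637 genes, 487 higher and 1150 lower, against 947.4 by chance, and 2447 genes passed with library weights. The groups did not overlap in 15.2% of genes, where chance gives 10%. The genes at an unadjusted p under 0.05 numbered 494 without WT_MSC 2, 828 without WT_MSC 3 and 2914 without the library labelled KO_MSC 1.

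Since no gene passed, the members of each list are counted as adjusted over the list alone. Of 18 stromal identity genes 9 were lower adjusted over the list alone (median -1.36, and -1.59 and -1.21 within batches 1 and 2). Camera called stromal identity (adjusted p = 8.76e-10, and adjusted p = 0.339 with an estimated correlation). Of 19 extracellular matrix genes 14 were lower adjusted over the list alone (median -1.79, within batches -1.06 and -2.18). Camera called extracellular matrix (adjusted p = 1.8e-11, and adjusted p = 0.339 with an estimated correlation). All 15 adipocyte genes were lower and 3 were so adjusted over the list alone (median -1.23, within batches -0.41 and -1.67), with the lipid carrier gene Apoe at -2.30 ± 0.63 and Pparg, the main regulator of fat cell formation, at -1.64 ± 0.41. Camera called adipocyte genes (adjusted p = 3.28e-05, and adjusted p = 0.339 with an estimated correlation). Without the library labelled KO_MSC 3 their median was -0.64.

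Of 10 mesenchymal transcription factors 3 were lower adjusted over the list alone (median -0.72, within batches -0.68 and -0.9996). The list also holds the adhesion gene Cdh2 (-2.14 ± 0.42), and Snai2 was at -1.44 ± 0.45. Camera called mesenchymal transcription factors (adjusted p = 0.00142, and adjusted p = 0.339 with an estimated correlation), but not without the library labelled KO_MSC 1 (0.190) or in batch 2 alone (0.109). All 14 interferon response genes were lower and 2 were so adjusted over the list alone (median -0.54, within batches -0.80 and -0.54), with the antiviral genes Ifit1 at -2.79 ± 0.65 and Oasl2 at -2.16 ± 0.43. Camera called interferon response (adjusted p = 0.00138, and adjusted p = 0.547 with an estimated correlation), but not without the library labelled KO_MSC 1 (0.190), without the library labelled KO_MSC 2 (0.0521) or in batch 2 alone (0.109). Of 16 osteoblast genes 12 were lower and 0 were so adjusted over the list alone (median -1.16, within batches -0.58 and -1.23), with Runx2 and Dlx5, transcription factors of bone formation, at -1.11 ± 0.48 and -1.51 ± 0.47. Camera called osteoblast genes (adjusted p = 0.0174, and adjusted p = 0.68 with an estimated correlation), but not without WT_MSC 2 (0.238), WT_MSC 3 (0.0854) or the library labelled KO_MSC 1 (0.871), nor in batch 2 alone (0.207). Without the library labelled KO_MSC 3 the medians of osteoblast genes and interferon response were -0.72 and -0.98, and without the library labelled KO_MSC 2 that of interferon response was -0.25.

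Of 16 ribosomal protein genes 15 were higher and 1 was so adjusted over the list alone (median 1.10, within batches 0.82 and 1.30), with Rps2 at 1.93 ± 0.41 and Rps6 at 1.19 ± 0.39. Reads of these genes can be shared with their many pseudogenes. Camera called ribosomal protein genes (adjusted p = 8.76e-10, and adjusted p = 0.339 with an estimated correlation). Of 24 proliferation genes 15 were higher and 0 were so adjusted over the list alone (median 0.50, within batches 1.11 and 0.17), with the mitotic kinase gene Cdk1 at 1.97 ± 0.54, Birc5 at 1.61 ± 0.46 and Pcna at 1.43 ± 0.44. Camera called proliferation (adjusted p = 0.00913, and adjusted p = 0.68 with an estimated correlation), but not without WT_MSC 2 (0.298), the library labelled KO_MSC 1 (0.532) or the library labelled KO_MSC 2 (0.143), in batch 2 alone (0.222) or with quantile scaling (0.0762). The median of proliferation was -0.05, 0.28 and 1.31 without the libraries labelled KO_MSC 1, 2 and 3, and 0.01 without WT_MSC 2. Of 10 neutrophil and granulocyte markers, which the CD45 gate should remove, 8 were higher and 0 were so adjusted over the list alone (median 1.09, within batches 1.58 and 0.77). Camera called neutrophil and granulocyte markers (adjusted p = 0.0332, and adjusted p = 0.68 with an estimated correlation), but not without WT_MSC 3 (0.458) or the library labelled KO_MSC 1 (0.780), in batch 2 alone (0.0717) or with quantile scaling (0.0655). Their median was -0.14 without the library labelled KO_MSC 1, in which their mean level was 12.02, against 7.07 to 10.41 in the other 5 MSC libraries. It was 1.91 without the library labelled KO_MSC 3, 1.86 without WT_MSC 1 and 0.14 without WT_MSC 3.

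The other lists were not called. Their medians were -0.09 for p53 target genes, with the cell death genes Bax at 0.84 ± 0.45 and Fas at -1.34 ± 0.66, -0.15 for chondrocyte genes, -0.02 for myogenic program, 0.01 for mature skeletal muscle and -0.10 for smooth muscle genes. They were 0.04 for hypoxia and glycolysis, -0.26 for inflammatory secretory genes, -0.10 for immediate early and heat shock genes, -0.35 for genes altered in sarcoma, and 0.93 for sex-linked genes. Markers of macrophages, lymphocytes, erythroid and endothelial cells had medians of 0.11, 0.08, 0.30 and 0.02. Without single libraries the median ranged from -0.47 to -0.007 for genes altered in sarcoma, 0.04 to 1.79 for sex-linked genes, 0.06 to 1.32 for erythroid markers, -0.40 to -0.05 for inflammatory secretory genes and -0.25 to -0.12 for smooth muscle genes. With upper-quartile scaling the medians of p53 target genes, myogenic program, smooth muscle genes and immediate early and heat shock genes turned to 0.02, 0.08, 0.005 and 0.002, and that of chondrocyte genes turned to 0.13 with quantile scaling. The median of erythroid markers was -0.24 within batch 1 and 0.98 within batch 2, and that of sex-linked genes -0.65 and 1.77. Within batch 1 the medians of p53 target genes, chondrocyte genes and genes altered in sarcoma were 0.07, 0.19 and 0.06, and within batch 2 that of inflammatory secretory genes was 0.03. The means of mature skeletal muscle and of hypoxia and glycolysis were -0.04 and -0.05, opposite to their medians, and camera's direction for p53 target genes was up, opposite to their median. Camera called erythroid markers without WT_MSC 1 (0.000921), without the library labelled KO_MSC 3 (0.0187) and in batch 2 alone (0.00744), smooth muscle genes without the library labelled KO_MSC 3 (0.0183), and macrophage markers without WT_MSC 2 (0.0310). In smooth muscle genes and genes altered in sarcoma 1 gene each was lower adjusted over the list alone, and in the others 0 genes. The genes with the smallest unadjusted p included Socs2 (-2.58 ± 0.43), an inhibitor of cytokine signaling, Angpt2 (-2.13 ± 0.40), Synpo (-1.90 ± 0.36) and Ttyh2 (-2.04 ± 0.38), each with an adjusted p of 0.551 in limma.

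**Figure D2:**
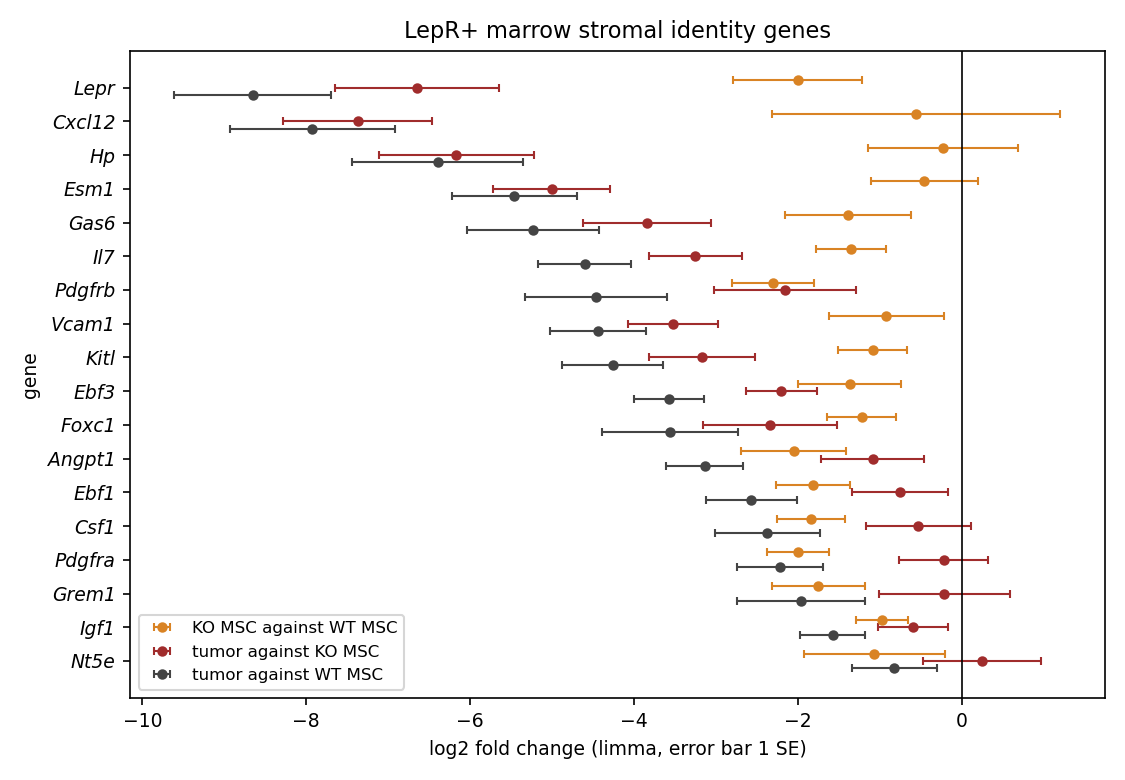
Log2 fold changes (x axis; points with 1 SE) of the 18 LepR+ marrow stromal identity genes (y axis) in the 3 comparisons. All 18 lie below 0 in libraries labelled KO MSC against WT MSC and in tumors against WT MSC, where Lepr reaches -8.65. MSCs were sorted for LepR and CD140a, and no sort is described for tumors.

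The second comparison set tumors against the libraries labelled KO MSC. In tumors 10 of 12 macrophage markers, 5 of 10 endothelial markers and 4 of 19 extracellular matrix genes rose, as did the cell cycle genes Ccnd1 and Cdkn2a. Of the stromal identity genes 9 of 18 fell, and of neutrophil and granulocyte markers 6 of 10. Of erythroid markers 3 of 11 fell, with a median below 0 in batch 1 and above 0 in batch 2. Limma called 944 genes, 512 higher and 432 lower, of which 930 changed at least 2-fold. Large rises included macrophage genes. Ccl8 (chromosome 11, 82115185 to 82116799), a monocyte chemokine, rose by 8.40 ± 1.18 (SE, n = 3 and 6; adjusted p = 0.00447, limma), C1qb by 7.63 ± 1.03, Ctss by 7.59 ± 0.85, Ms4a7 by 7.39 ± 0.82 and Aif1 by 6.67 ± 0.77. Large falls included Car1, an erythroid carbonic anhydrase (-7.96 ± 0.83), Cxcl12, the chemokine that holds blood stem cells in the marrow (-7.37 ± 0.91), the leptin receptor gene Lepr (-6.65) and the fat cell hormone gene Adipoq (-6.60 ± 0.92). The groups did not overlap in 13.4% of genes, where chance gives 2.38%.

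Of 12 macrophage markers 10 rose, 0 fell and 2 did not pass, and 11 rose adjusted over the list alone (median 5.16, within batches 5.19 and 5.76). They included the signaling adaptor gene Tyrobp (6.54 ± 0.81). Camera called macrophage markers (adjusted p = 9.34e-12, and adjusted p = 0.334 with an estimated correlation). Of 10 endothelial markers 5 rose and 5 did not pass, and 8 rose adjusted over the list alone (median 2.32, within batches 1.76 and 2.44), among them the junction genes Cdh5 (2.93 ± 0.49) and Cldn5 (3.05 ± 0.59). Camera called endothelial markers (adjusted p = 8.18e-07, and adjusted p = 0.354 with an estimated correlation). Of 10 lymphocyte markers 2 rose and 8 did not pass, and 3 rose adjusted over the list alone (median 1.43, within batches 0.06 and 2.24). Those that rose were the T cell receptor complex genes Cd3d (2.59 ± 0.54) and Cd3g (2.31 ± 0.57). Camera called lymphocyte markers (adjusted p = 0.00792, and adjusted p = 0.367 with an estimated correlation), but not without tumor 6 (0.0533) or with the replicate block (median 0.59, adjusted p = 0.0736). The CD45 and CD31 gates should remove these cells from MSCs, and no such sort is described for tumors, although their labels give tumor cell as the cell type.

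Of 19 extracellular matrix genes 4 rose, 0 fell and 15 did not pass, and 7 rose adjusted over the list alone (median 1.77, within batches 1.26 and 2.10). They were the fibronectin gene Fn1 (6.57 ± 0.89), Postn (5.56 ± 1.32), the protease inhibitor gene Timp1 (4.27 ± 0.73) and Col6a3 (3.67 ± 0.64). Camera called extracellular matrix (adjusted p = 0.000375, and adjusted p = 0.354 with an estimated correlation). Of 10 mesenchymal transcription factors Twist1 (1.85 ± 0.41) and Tcf4 (2.07 ± 0.51) rose and 8 did not pass, and 3 rose adjusted over the list alone (median 0.87, within batches 1.15 and 0.35). Camera called mesenchymal transcription factors (adjusted p = 0.0366, and adjusted p = 0.354 with an estimated correlation), but not without the library labelled KO_MSC 1 (0.111), tumor 1 (0.0573) or tumor 2 (0.0908), nor in batch 2 alone (0.488). Their median was 0.55 without the library labelled KO_MSC 1 and 0.56 without tumor 4, and that of extracellular matrix was 1.14 without the library labelled KO_MSC 3 and 1.06 without tumor 4.

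Of 18 genes altered in sarcoma 4 rose, 1 fell and 13 did not pass, with 7 higher and 5 lower adjusted over the list alone. Ccnd1, which encodes cyclin D1 (chromosome 7, 144929931 to 144939925), rose by 5.87 ± 0.71 and Ccnd2 by 2.92 ± 0.49. Cdkn2a, which encodes the inhibitors p16 and ARF (chromosome 4, 89274471 to 89294653), rose by 3.75 ± 0.80, and the cyclin E gene Ccne1 fell by 2.34 ± 0.48. The list was not called (median 0.35, camera adjusted p = 0.232). Of 10 smooth muscle genes Acta2 (5.21 ± 0.79) and Actg2 (1.57 ± 0.33), which encode smooth muscle actins, rose and 3 rose adjusted over the list alone, but the list was not called (median 0.40, camera adjusted p = 0.0826), except without tumor 2 (0.0437). Of 26 p53 target genes 1 rose, the kinase gene Plk2 (2.23 ± 0.52), also when adjusted over the list alone, and the list was not called (median 0.32). The cell cycle inhibitor gene Cdkn1a, at 2.26 ± 0.71, did not pass (adjusted p = 0.0838, limma).

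Of 18 stromal identity genes 9 fell and 9 did not pass, and 11 fell adjusted over the list alone (median -2.27, within batches -1.98 and -2.87). They included Hp (-6.17 ± 0.94) and Esm1 (-5.00 ± 0.71). Camera called stromal identity (adjusted p = 5.01e-09, and adjusted p = 0.334 with an estimated correlation). The list holds Lepr and Pdgfra, for whose products MSCs were sorted, and no sort is described for tumors. The fall of the list could therefore come from the sort alone. Of 10 neutrophil and granulocyte markers 6 fell and 4 did not pass, and 8 fell adjusted over the list alone (median -3.84, within batches -6.62 and -2.001). They included the granule protease genes Elane (-5.66 ± 1.15) and Prtn3 (-4.49 ± 0.88). Camera called neutrophil and granulocyte markers (adjusted p = 1.18e-06, and adjusted p = 0.354 with an estimated correlation). Of 11 erythroid markers 3 fell and 8 did not pass, and 4 fell adjusted over the list alone, among them the transcription factor gene Klf1 (-5.89 ± 0.71) and Ermap (-4.68 ± 0.73). Camera called erythroid markers (adjusted p = 0.00586, and adjusted p = 0.46 with an estimated correlation), also in batch 2 alone (0.00782). However, their median of -0.69 was -2.69 within batch 1 and 0.35 within batch 2. It was -0.30 and -1.095 without the libraries labelled KO_MSC 1 and KO_MSC 3, -0.38, -0.27 and -1.25 without tumors 3, 4 and 6, and -1.63 with quantile scaling.

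Of 24 proliferation genes the DNA replication genes Mcm5 (-3.08 ± 0.62) and Rrm2 (-2.54 ± 0.56) fell and 22 did not pass, and 5 fell adjusted over the list alone (median -0.84, within batches -2.50 and -0.36). Camera called proliferation (adjusted p = 0.000375, and adjusted p = 0.461 with an estimated correlation). Its median was -0.48, -0.45 and -2.10 without the libraries labelled KO_MSC 1, KO_MSC 2 and KO_MSC 3, and -1.56 with quantile scaling. Of 12 immediate early and heat shock genes the chaperone gene Dnajb1 (-1.60 ± 0.36) and the transcription factor gene Fosb (-2.47 ± 0.56) fell and 10 did not pass, and 7 fell adjusted over the list alone (median -1.64, within batches -2.12 and -0.96). Camera called immediate early and heat shock genes (adjusted p = 0.000375, and adjusted p = 0.354 with an estimated correlation). A sort is described for MSCs alone, so the fall of this list in tumors cannot be told apart from the preparation. Of 14 interferon response genes Oas1a rose (2.44 ± 0.58) and 13 did not pass, and 5 rose adjusted over the list alone (median 1.10, within batches 0.96 and 1.27). Camera called interferon response (adjusted p = 0.000505, and adjusted p = 0.354 with an estimated correlation).

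Of 16 ribosomal protein genes 2 rose, also when adjusted over the list alone, and 14 did not pass, with Rpl19 (1.99 ± 0.44) among those that rose (median 1.10, within batches 1.69 and 1.05). Camera called ribosomal protein genes (adjusted p = 0.000375, and adjusted p = 0.354 with an estimated correlation), but not with quantile scaling (median 0.36, adjusted p = 0.265) or in batch 2 alone (0.0839). Of 15 hypoxia and glycolysis genes the hexokinase gene Hk2 rose (2.00 ± 0.49) and 14 did not pass, and 2 rose adjusted over the list alone (median 1.40, within batches 0.66 and 1.59). Camera called hypoxia and glycolysis (adjusted p = 0.00988, and adjusted p = 0.354 with an estimated correlation). Of 12 mature skeletal muscle genes 0 passed over all genes or adjusted over the list alone, and all 12 changes were positive (median 2.64, within batches 2.52 and 3.22). Camera called mature skeletal muscle (adjusted p = 0.00196, and adjusted p = 0.461 with an estimated correlation). Osteoblast genes (median 0.35, within batches 1.59 and -0.62), chondrocyte genes (0.10), myogenic program (0.61) and sex-linked genes (-0.73) were not called and had 0 passing genes, also when adjusted over the list alone. Camera called osteoblast genes in batch 2 alone (median -0.71, adjusted p = 0.0236), and myogenic program without the library labelled KO_MSC 2 (0.0495) and without tumors 2, 5 or 6 (0.00944, 0.0243 and 0.0360). Of 15 adipocyte genes 2 fell, Lpl by 3.62 ± 0.87 among them, with 1 higher and 3 lower adjusted over the list alone, and their median was 0.15, their mean -0.20 and their median -0.001 with quantile scaling. Of 12 inflammatory secretory genes 1 rose, the chemokine gene Ccl7 (4.51 ± 0.99), also when adjusted over the list alone (median 0.58).

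The number of called genes depended on single libraries. It was 113 without the library labelled KO_MSC 1 (41 higher, 72 lower), 396 without the library labelled KO_MSC 2, 1627 without the library labelled KO_MSC 3 (704 higher, 923 lower), 597 without tumor 5 and 621 without tumor 6. Quantile scaling called 1545 genes, 33.7% of them higher, where the values as deposited gave 54.2% higher, and batch 2 alone gave 229.

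The third comparison set tumors against WT MSC. In tumors 11 of 12 macrophage markers, 9 of 10 endothelial markers and 14 of 16 ribosomal protein genes rose and 16 of 18 stromal identity genes fell, but camera called none of these lists with an estimated correlation, except stromal identity with the batch term. Limma called 4033 genes, 1970 higher and 2063 lower, of which 3665 changed at least 2-fold. Lepr (chromosome 4, 101717404 to 101815352) fell by 8.65 ± 0.95 (SE, n = 3 and 6; adjusted p = 0.000992, limma). MSCs were sorted for LepR and CD140a, and no sort is described for tumors. Lower Lepr and stromal identity values in tumors could therefore come from the sort alone. Cxcl12 (-7.93 ± 1.01), the kininogen gene Kng1 (-7.69 ± 0.74), Chrdl1 (-7.39 ± 0.67) and the elastic fiber gene Fbln5 (-6.40 ± 0.90) also fell. Ccl8 rose by 8.52 ± 1.23, Ms4a7 by 7.44 ± 0.83, Tyrobp by 7.14 ± 0.90 and H2-Aa, a chain of MHC class II, by 6.98 ± 1.04. Timp1 rose by 4.60 ± 0.35 (adjusted p = 0.000638, limma). The groups did not overlap in 25.2% of genes, where chance gives 2.38%.

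Of 18 stromal identity genes 16 fell and 2 did not pass, and 17 fell adjusted over the list alone (median -3.92, within batches -3.31 and -4.20). They included Il7, a growth factor of lymphoid precursors (-4.60 ± 0.57), and Ebf3 (-3.57 ± 0.42). Camera called stromal identity (adjusted p = 6.98e-11, and adjusted p = 0.276 with an estimated correlation, or 0.0480 with the batch term as well). Of 15 adipocyte genes 5 fell, 1 rose and 9 did not pass, with 7 lower and 1 higher adjusted over the list alone (median -0.48, within batches -0.15 and -1.01). Lpl, a lipase (-5.35 ± 0.86), and Pparg (-3.56 ± 0.46) fell. Camera called adipocyte genes (adjusted p = 0.0271, and adjusted p = 0.606 with an estimated correlation), but not without WT_MSC 3 (0.0531) or tumor 6 (0.0585). It did not call them with the replicate block either (median -0.86, adjusted p = 0.0678). Their median was -0.94 without WT_MSC 1, -1.16 without tumor 4 and -1.18 with quantile scaling. Of 12 immediate early and heat shock genes 6 fell and 6 did not pass, with 7 lower and 1 higher adjusted over the list alone (median -1.69, within batches -2.80 and -0.66), among them Fos (-3.95 ± 0.61) and Egr1 (-2.75 ± 0.83). Camera called immediate early and heat shock genes (adjusted p = 0.00736, and adjusted p = 0.57 with an estimated correlation), but not in batch 2 alone (0.0664). Without WT_MSC 1 their median was -1.08. Since a sort is described for MSCs alone, their fall in tumors cannot be told apart from the preparation.

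Of 10 neutrophil and granulocyte markers 3 fell and 7 did not pass, and 4 fell adjusted over the list alone, with the granule enzyme gene Mpo at -5.24 ± 1.05. Camera called neutrophil and granulocyte markers (adjusted p = 0.00736, and adjusted p = 0.606 with an estimated correlation), but their median of -2.11 was -5.23 within batch 1 and -0.06 within batch 2, and batch 2 alone gave no call (0.193). Without WT_MSC 1 it was -0.90. Of 11 erythroid markers 3 fell, also when adjusted over the list alone, among them Klf1 (-4.99 ± 0.71) and Ermap (-4.58 ± 0.54). The median of erythroid markers was -0.39, with -4.08 within batch 1 and 1.13 within batch 2. Camera did not call them (adjusted p = 0.134), but it did with quantile scaling (0.0496), without WT_MSC 2 (0.0496) and without tumor 6 (0.0275).

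Of 12 macrophage markers 11 rose and 1 did not pass, and 12 rose adjusted over the list alone (median 5.85, within batches 5.31 and 5.94), including the Fc receptor chain gene Fcer1g (5.90 ± 0.67). Camera called macrophage markers (adjusted p = 1.11e-09, and adjusted p = 0.276 with an estimated correlation). Of 10 endothelial markers 9 rose and 1 did not pass, and 10 rose adjusted over the list alone (median 2.37, within batches 2.36 and 2.59), including Cdh5 (2.97 ± 0.45) and Kdr, a receptor for vascular endothelial growth factor (2.40 ± 0.50). Camera called endothelial markers (adjusted p = 2.95e-06, and adjusted p = 0.375 with an estimated correlation). Of 10 lymphocyte markers 3 rose, also when adjusted over the list alone (median 1.60, within batches 0.48 and 2.33), among them Cd3d (2.71 ± 0.51). Camera called lymphocyte markers (adjusted p = 0.0077, and adjusted p = 0.57 with an estimated correlation). Without tumor 5 their median was 1.06. Over 13 alternatives it ranged from 0.61 to 2.33, and camera called the list in all 13.

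Of 16 ribosomal protein genes 14 rose and 2 did not pass, and 15 rose adjusted over the list alone (median 2.27, within batches 2.43 and 2.27), among them Rps18 (3.53 ± 0.56) and Rpl19 (2.68 ± 0.38). Camera called ribosomal protein genes (adjusted p = 7.99e-10, and adjusted p = 0.276 with an estimated correlation). Their median was 1.42 with quantile scaling. Of 15 hypoxia and glycolysis genes 4 rose and 11 did not pass, with 6 higher and 1 lower adjusted over the list alone (median 1.71, within batches 1.04 and 1.89). The glycolytic enzyme genes Pgk1 (2.23 ± 0.35) and Hk2 (2.36 ± 0.48) and the carbonic anhydrase gene Car9 (1.03 ± 0.30) rose. Camera called hypoxia and glycolysis (adjusted p = 0.024, and adjusted p = 0.57 with an estimated correlation), but not with quantile scaling (median 0.57, adjusted p = 0.061) or in batch 2 alone (0.0664). Of 12 mature skeletal muscle genes 0 passed over all genes or adjusted over the list alone (median 2.70, within batches 3.11 and 2.93). Camera called mature skeletal muscle (adjusted p = 0.00822, and adjusted p = 0.788 with an estimated correlation), but not in batch 2 alone (0.0664). Without tumor 4 their median was 1.77.

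Of 26 p53 target genes 5 rose, 2 fell and 19 did not pass, with 6 higher and 2 lower adjusted over the list alone, and the list was not called (median -0.13, mean 0.15, camera adjusted p = 0.54). Cdkn1a rose by 2.42 ± 0.46, Pmaip1 by 2.12 ± 0.48 and Bax by 1.88 ± 0.30, of which Pmaip1 and Bax promote cell death, and the DNA repair gene Xpc fell by 1.86 ± 0.33. Of 18 genes altered in sarcoma 4 rose and 3 fell, with 5 higher and 4 lower adjusted over the list alone, and the list was not called (median -0.12, mean 0.52, camera adjusted p = 0.776). Ccnd1 rose by 5.52 ± 0.71, Cdkn2a by 3.75 ± 0.79 and its neighbor Cdkn2b (chromosome 4, 89306299 to 89311039) by 3.88 ± 0.82, and the receptor kinase gene Kit fell by 2.99 ± 0.33. Cdkn2a lay at the floor of its batch in all 6 MSC libraries (4.27 or 5.24), so its change is understated.

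Extracellular matrix genes moved in both directions. Of 19, 4 rose and 2 fell, with 4 higher and 3 lower adjusted over the list alone (median -0.45, mean 0.18, camera adjusted p = 0.842), and Fn1 rose by 5.68 ± 0.97 while Fbn1 fell by 2.75 ± 0.63. Of 24 proliferation genes 2 rose and 8 fell, with 2 higher and 9 lower adjusted over the list alone, and Cdk1 rose by 1.79 ± 0.49 while Mcm6 fell by 1.98 ± 0.49. Proliferation was not called (median -0.64, camera adjusted p = 0.134), but it was with quantile scaling (0.023) and without WT_MSC 2 (0.00219). Of 10 mesenchymal transcription factors 1 rose and 2 fell, also when adjusted over the list alone (median 0.30), Twist1 by 1.18 ± 0.31, Cdh2 (-2.33 ± 0.52) and Snai2 (-1.91 ± 0.42). Of 10 smooth muscle genes 3 rose and 1 fell, also when adjusted over the list alone (median 0.21), among them Acta2 (5.31 ± 0.74) and the kinase gene Mylk (-2.22 ± 0.70). Of 14 interferon response genes Isg15 (2.03 ± 0.57) and Oas1a (1.98 ± 0.58) rose, also when adjusted over the list alone (median 0.51). Of 12 inflammatory secretory genes Ccl7 (4.15 ± 0.95) and Nfkbia (1.48 ± 0.45) rose and Icam1 fell (-2.82 ± 0.50), with 2 higher and 2 lower adjusted over the list alone (median 0.50). Osteoblast genes had a median of -0.59 (0.60 and -1.20 within batches) and 0 passing genes, also when adjusted over the list alone, with Phex at -2.43 ± 0.92, and camera called them in batch 2 alone (0.0284). In chondrocyte genes (median 0.16) 1 fell and in myogenic program (0.54) 1 rose, and 0 did so adjusted over the list alone. Without tumor 2 camera called myogenic program (0.0374). Sex-linked genes had 0 passing genes, also when adjusted over the list alone, and a median of -0.003 that was 0.08 to 0.11 with the other scalings.

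Without WT_MSC 1, 2 or 3 the number of called genes was 1856, 2339 and 2268. Batch 2 alone gave 775 genes.

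**Figure D3:**
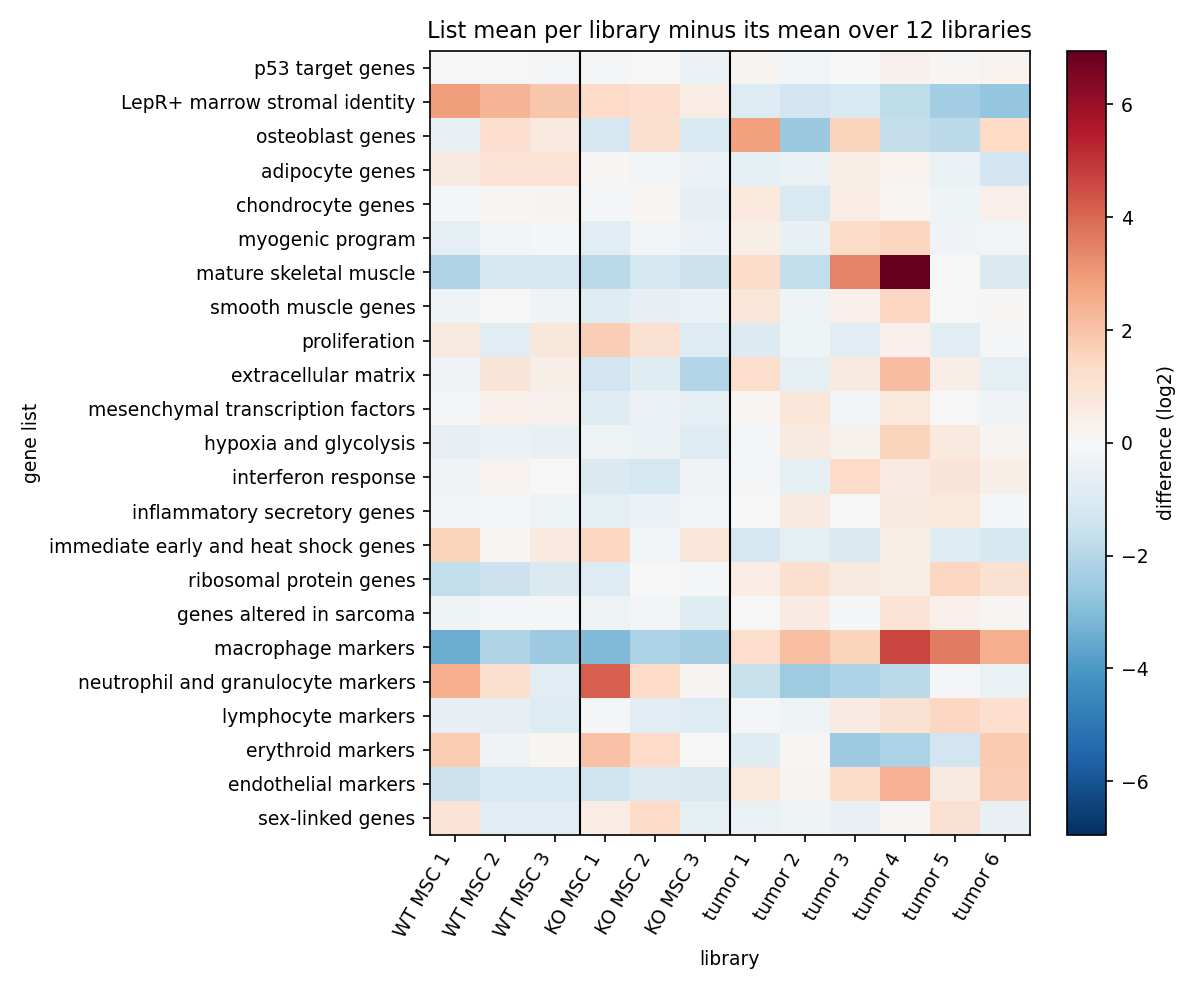
Mean level of each of the 23 gene lists (y axis) in each of the 12 libraries (x axis), as the difference in log2 units from the list's mean over all libraries (color). Macrophage markers are higher in all 6 tumors than in all 6 MSC libraries, and the mean level of mature skeletal muscle reaches 13.78 in tumor 4.

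The changes of libraries labelled KO MSC and of tumors, both against the same WT MSC libraries, were compared across 18948 genes, which are not independent replicates. Pearson's r was 0.501, where simulated unchanged groups against the same controls gave 0.300 (0.275 to 0.323 in 100 simulations). The simulations drew each gene independently, whereas measured genes move together. The simulated ranges here and below are therefore too narrow to judge an excess. The covariance was 0.413 against a simulated 0.0632, a difference of 0.350. The direction was the same in 62.9% of genes, where the simulated groups gave 61.5% (60.7 to 62.5). Of the 487 genes higher at an unadjusted p under 0.05 in libraries labelled KO MSC, 212 were among the 1970 that rose in tumors, and 467 of the 1150 lower genes were among the 2063 that fell. Simulated unchanged groups against the same controls, with lists of these sizes taken by p, shared 160.2 (138 to 187) and 335.6 (285 to 379) in 100 simulations, and independent lists would share 50.6 and 125.2. The 3 controls could not be split with at least 2 on each side. The simulated groups shared far more genes than independent lists would. No gene changed in them, so their lists were picked by spread alone. Of the 4033 genes called in tumors, 3665 changed at least 2-fold. The simulated overlap, r and share of directions therefore do not say how much of the observed agreement comes from shared controls.

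The tumors differed widely from one another. Gap tests for a single outlying tumor, given below, did not flag the lists named here, and the differences were otherwise not tested. The list with the widest range was mature skeletal muscle, with means of 8.11, 5.14, 10.27, 13.78, 6.86 and 5.83 in tumors 1 to 6. Osteoblast genes had means of 13.14, 7.75, 11.87, 8.67, 8.50 and 11.70. Of the 10 genes with the largest SD among tumors, the bone matrix gene Ibsp was at 19.26, 8.79, 16.22, 8.56, 9.35 and 16.00 in tumors 1 to 6, and Bglap, the osteocalcin gene, at 16.84, 8.51, 15.65, 7.06, 11.31 and 14.94. The muscle actin gene Acta1 was at 19.28 in tumor 4, at 14.04 in tumor 3 and at 6.67 to 9.94 in the others. Ckm, a muscle creatine kinase, was at 16.30 in tumor 4, at 10.67 in tumor 3 and at 5.11 to 8.41 in the others. Crabp1, a retinoic acid binding protein, ranged from 4.52 in tumor 3 to 17.33 in tumor 2.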

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

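The tests of explanations in this part were chosen after the results were seen. The counts of other splits and the gap tests of list means were planned, and the gap tests of genes ran on genes named from these data. Gap tests ran on 23 list means and 82 genes in the 6 tumors, and 3 passed. Chance passes about 1 in 20, so chance alone could give as many. Tumor 4 stood above the others for immediate early and heat shock genes, with a mean of 9.45 against 7.86 to 8.33. Tumor 5 stood above the others for sex-linked genes, with a mean of 7.496 against 5.93 to 6.52. Tumor 6 stood below the others for Fbn1, at 7.10 against 9.04 to 10.12.

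For KO MSC against WT MSC, the 10 splits of the 6 libraries are too few for a share under 0.05. The real split called 0 genes in limma, the highest of the others 0, and all 10 gave as many, with 1637 genes at an unadjusted p under 0.05 against at most 1195. The real split called 9 lists and the highest other 13, and 3 of 10 called as many. For tumor against KO MSC, 1 of 84 splits, the real one, called 944 genes, and the highest other called 224. This is the smallest share that 84 splits can give, so chance is unlikely but not excluded. For the number of lists chance stays open, since 6 of 84 splits called 14 or more and the highest other called 16. For tumor against WT MSC, 1 of 84 splits, the real one, called 4033 genes, and the highest other called 279, so chance is again unlikely. For its lists chance stays open, since 15 of 84 splits called 10 or more and the highest other called 13. The splits do not separate a tumor change from the sort, which is described for MSCs alone.

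The 3 libraries labelled KO MSC did not share a low Trp53 value. A swap of labels with the WT MSC group cannot be told apart, since the lowest WT value, 9.96, lay above all 6 tumors but the library labelled KO_MSC 1, at 10.49, shows that a library labelled KO MSC can have such a value. The low value in the library labelled KO_MSC 3 may be gene dropout, since 7.54% of 1339 genes of similar WT level lay as far below it there. Other cells would have an intact gene only if the deletion was limited to some cells, and the knockout allele is not given in the sources used here. If so, RNA of such cells cannot be told apart from a transcript left by the deletion. Haematopoietic markers were 2.11 higher in the libraries labelled KO_MSC 1 and KO_MSC 2 than in the library labelled KO_MSC 3, and no value bounds their share of Trp53. A single wrong label also stays open, untested.

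The stromal identity genes were lower in the libraries labelled KO MSC. The tables argue against the library labelled KO_MSC 3 as the cause, since without it the median was -1.08 and 18 of 18 genes stayed lower. Both groups divide the same way between the batches, so an added batch shift cancels from their difference by design. The medians of -1.59 within batch 1 and -1.21 within batch 2 could not test such a shift. They show only that both batches held the difference. Dilution by haematopoietic RNA cannot be told apart with 6 libraries, over which Pearson's r between haematopoietic and stromal levels was 0.169 (exact permutation p = 0.746, adjusted 0.746 over 5 relations; Spearman's rho 0.2, p = 0.714), -0.145 without the 2 farthest libraries and likewise within the 4 libraries of batch 2, and 0.933 after removal of group means. The medians of the other 9 splits were at most 1.07 in size. The p53 genotype stays open and untested, since Trp53 did not follow the labels.

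Mature skeletal muscle genes were high in tumors 3 and 4. Muscle tissue beside the tumor and a myogenic program of tumor cells cannot be told apart. Neither test reached its mark in both tumors, and the marks were set after the values were seen. The myogenic program list minus the mature list was -3.10 in tumor 3 and -6.38 in tumor 4. The mark for adjacent muscle was a difference of less than -4 in both. The mean of the myogenic program list was 7.17 in tumor 3 and 7.40 in tumor 4. The mark for a tumor program was a mean of more than 8 in both. Both marks were set without a reference sample of muscle, so reaching or missing them cannot decide between these causes. No group of the labels separates these tumors.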

How the results depend on the processing

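All alternatives were planned except the batch term, batch 2 alone and the centring of the tumors, which were chosen after the data were seen. Pseudocounts and count tests were not run, because the values are logarithms from which reads cannot be recovered, and of TMM or upper-quartile scaling the latter was run. The unknown depth limits all counts, and the low complexity of the library labelled KO_MSC 3 limits those of the 2 comparisons that include it. The named genes followed numbered 39, 49 and 56 for KO against WT MSC, tumor against KO MSC and tumor against WT MSC. All kept their direction in each alternative. They were picked from these same data by large changes without overlap or by small p-values, so a kept direction was largely fixed in advance. Of the 0, 43 and 55 named genes that passed, 0, 9 and 26 passed in all alternatives. Library weights called 2447, 4821 and 6821 genes, but their estimation stopped before it converged in 2 of the 3 comparisons, and the weights of single libraries ran from 0.231 to 6.63. The Trp53 change passed with weights in tumor against KO MSC (-1.77) and ranged there from -2.255 without the library labelled KO_MSC 3 to -0.49 without the library labelled KO_MSC 1, and in tumor against WT MSC it did not pass in batch 2 alone (-2.61) and ranged from -2.59 to -2.11 without single libraries. For tumor against KO MSC the count was 1423 with the stricter filter, where fewer genes were tested, 1545 with quantile scaling, 1923 with all 12 libraries in 1 fit, 229 in batch 2 alone, with fewer libraries, and 113 to 1627 without single libraries. For tumor against WT MSC it was 775 in batch 2 alone and 1856 to 4737 without single libraries. The batch term gave 0, 827 and 3701 genes, with 789 and 3555 shared with the reported ones. With an estimated correlation 0 lists were called in each comparison, except stromal identity in tumor against WT MSC with the batch term (0.0480), and for KO against WT MSC 5 lists were called in batch 2 alone and 4 to 11 without single libraries. Upper-quartile scaling moved the median of all genes from -0.01 to 0.09 in KO against WT MSC and from -0.06 to 0.05 in tumor against WT MSC. The correlation of 0.501 was 0.458 to 0.553 without single WT MSC libraries, and the range of 8.64 among tumors was 8.40 and 8.25 with centring.

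The labels do not say whether the replicate numbers pair the libraries, and correlations among so few libraries cannot decide it. Same-numbered libraries had deviations correlated at 0.24, 0.15 and -0.15 (KO and WT MSC), -0.22, -0.07 and 0.22 (tumor and KO MSC) and -0.32, -0.09 and 0.01 (tumor and WT MSC), and not every library correlated best with its own number. With the replicate block 0, 34 and 1445 genes were called, and camera no longer called lymphocyte markers in tumor against KO MSC (0.0736) or adipocyte genes in tumor against WT MSC (0.0678), called myogenic program in both (0.0060 and 0.0297) and changed no other list call.

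Some list medians turned sign, and the cause was not tested. In KO against WT MSC these were myogenic program in the other table (0.012), and in batch 2 alone mature skeletal muscle (-0.60), hypoxia and glycolysis (-0.14), inflammatory secretory genes (0.031), lymphocyte markers (-0.34) and endothelial markers (-0.020). In tumor against KO MSC they were osteoblast genes (-0.71) and erythroid markers (0.35) in batch 2 alone. In tumor against WT MSC they were sex-linked genes in the other table (0.072), and p53 target genes (0.039), erythroid markers (1.13) and sex-linked genes (1.02) in batch 2 alone.

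Without single libraries, medians in KO against WT MSC ranged from -0.15 to 0.058 for p53 target genes, -0.32 to 0.15 for chondrocyte genes, -0.16 to 0.090 for myogenic program, -0.20 to 0.24 for mature skeletal muscle, -0.047 to 1.31 for proliferation, -0.061 to 0.20 for hypoxia and glycolysis, -0.51 to 0.50 for immediate early and heat shock genes, -0.18 to 0.30 for macrophage, -0.14 to 1.91 for neutrophil and granulocyte, -0.095 to 0.21 for lymphocyte and -0.14 to 0.17 for endothelial markers. In tumor against KO MSC they ranged from -0.064 to 0.65 for p53 target genes, -0.090 to 0.70 for osteoblast genes, -0.30 to 0.54 for adipocyte genes, -0.016 to 0.41 for chondrocyte genes, -1.77 to -0.026 for sex-linked genes, 0.16 to 0.66 for smooth muscle genes, 0.40 to 0.87 for myogenic program and 0.20 to 0.42 for genes altered in sarcoma. In tumor against WT MSC they ranged from -0.975 to 9.6e-05 for osteoblast genes, -0.13 to 0.29 for chondrocyte genes, -1.51 to 0.72 for erythroid markers, -0.23 to 0.77 for sex-linked genes, -0.82 to -0.023 for extracellular matrix, -0.26 to -0.0031 for genes altered in sarcoma, -0.21 to -0.025 for p53 target genes, -1.27 to -0.35 for proliferation, 0.085 to 0.56 for mesenchymal transcription factors, 0.041 to 0.37 for smooth muscle genes, 0.34 to 0.85 for myogenic program and 0.37 to 0.77 for interferon response.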

Other observations

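The tests in this part were all chosen after the results were seen. Osteoblast genes and Cdkn2a varied among tumors. The osteoblast list averaged 13.14, 7.75, 11.87, 8.67, 8.50 and 11.70 in tumors 1 to 6, and Cdkn2a was at 6.95, 10.43, 6.92, 9.88, 9.54 and 8.28, a relation that was not tested. Met, a growth factor receptor gene, was at 11.13 in tumor 4 and at 6.18 to 8.08 in the others, and was singled out after its values were seen.

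Sex-linked genes did not follow the groups. Xist, expressed from the inactive X chromosome, was at 7.90, 9.83 and 9.93 in WT_MSC 1, 2 and 3, at 8.66, 5.14 and 10.51 in the libraries labelled KO_MSC 1, 2 and 3 and at 10.48, 6.35, 10.17, 5.14, 10.74 and 10.40 in tumors 1 to 6. Ddx3y, on the Y chromosome, was at 8.48, 4.45 and 4.45 in WT MSC, at 7.22, 9.24 and 4.45 in libraries labelled KO MSC and at 5.06, 6.38, 5.06, 7.69, 9.34 and 5.24 in tumors. Both were well above their lowest values in WT_MSC 1, the library labelled KO_MSC 1 and tumor 5. The sex of the mice is not given in the sources used here.

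The sorted MSC libraries held transcripts of blood cell precursors that the CD45 and Ter119 gates should remove. Mpo was at 13.84, 13.59 and 10.41 in WT_MSC 1, 2 and 3 and at 16.69, 12.20 and 7.96 in the libraries labelled KO_MSC 1, 2 and 3. Klf1 was at 12.39, 8.92 and 10.89 and at 13.41, 11.42 and 10.06. Whether such precursors contribute to the proliferation genes cannot be told. Across the 6 MSC libraries the erythroid and proliferation lists had a Pearson's r of 0.809 (exact permutation p = 0.0653, adjusted 0.326 over 5 relations) and a Spearman's rho of 0.771 (exact permutation p = 0.103, adjusted 0.495). Without the 2 libraries farthest from the median, and likewise within the 4 libraries of batch 2, r was 0.76. The neutrophil and granulocyte list with proliferation had an r of 0.542 (exact permutation p = 0.265, adjusted 0.442), 0.691 without the 2 farthest libraries and -0.093 within batch 2, with a rho of 0.543 (exact permutation p = 0.297, adjusted 0.495). Both blood lists together had an r of 0.665 (exact permutation p = 0.167, adjusted 0.417), 0.307 without the 2 farthest libraries and likewise within batch 2, with a rho of 0.543 (exact permutation p = 0.297, adjusted 0.495). No relation passed the correction, so 6 libraries leave it open.

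Genes on chromosome 15 were higher in tumor 4, by a median of 0.82 over 261 genes against the median of the other tumors, after centring of each tumor. The next largest in size of 120 medians, 1 per tumor and chromosome, was -0.53, for chromosome 14 in the same tumor. Chromosome 15 was picked because its median was the largest. In tumors 1, 2, 3, 5 and 6 the median of chromosome 15 was -0.11, 0.49, -0.41, -0.23 and -0.31. A gain of the whole chromosome might have been the cause, but of 4 sets of genes in order of position the lowest median was 0.030, in the set nearest the start, against 0.75, 1.07 and 1.04 in the others. That argues against a gain of the whole chromosome, and a gain of part of it was not tested. Myc, which lies on chromosome 15, was at 12.20 in tumor 4 and at most 10.34 in the others.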
